A study of Homo sapiens with 12 samples.

How the data were processed

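Monocytes from blood cell collections of 6 donors were cultured for 7 days into DCreg or mDC, per the labels' protocols, and each group gave 6 libraries from the same donors. The labels call the comparison group mDC and the design text calls the cells matured with monophosphoryl lipid A sDC; they were taken as the same group because the numbers of libraries and donors match. DNA was bisulfite treated and made into libraries with the Accel-NGS Methyl-Seq kit, per the labels' protocols. The submitters' processing notes name Trimmomatic (read trimming), Bismark (bisulfite alignment and methylation calls), SAMtools and Picard (alignment files) and the genome build hg19, without versions. The kit adds a low-complexity tail to reads, and whether it was trimmed, like the caller of the regions, its thresholds and the way libraries were combined into group means, is not given in the sources used here.

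The data are the authors' deposited table of 7279 differentially methylated regions. The methylation level is deposited as a fraction from 0 to 1, with 1 value for mDC and 1 for DCreg per the file headers. The headers do not say how it was formed. It was taken here as the mean of the group and multiplied by 100 to give percent. The deposited difference equals mDC minus DCreg in all 7279 regions and was recoded here as DCreg minus mDC in percentage points. The area statistic is a score per region deposited by the authors, per the file headers; its sign was opposite to that of the difference in 22 regions, and it was used only to describe regions and, in a later alternative, to leave those 22 out. The table also gives the number of CpG sites (at least 4, median 4, largest 150, with 54.9% of regions at exactly 4), the length (median 174 bp, interquartile range 90 to 303 bp), the nearest transcript, the distance to its TSS and an annotation class. The deposited length is end minus start plus 2 in every region, so the printed start or end may be off by 1 bp. Coverage per site was not used here, so the depth and the precision of a level are unknown, no interval is given for a level, and a region with few CpG sites may rest on few reads.

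All regions of the table had an absolute difference of at least 5.0 points. They were chosen by the authors for a difference, so that difference was not tested again. Regions are counted once each, and tests over regions or genes describe the calls, not the variation between donors. Classes are the deposited short annotation classes under descriptive names, with untranslated regions split off by the longer deposited annotation. They are promoter within 1 kb of a TSS, 1 to 50 kb from a TSS on either side (largest distance 49976 bp, which includes regions inside genes), intron, exon, untranslated region, downstream flank and intergenic. A region 1 to 50 kb from a TSS and inside a transcript is described as inside the gene, since the deposited class does not separate its exons from its introns.

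A region was given the gene name of the table, 6916 regions to 3729 names; 363 regions had none. Of these names, 3348 were current symbols and 226 older symbols in a RefSeq gene table of GRCh38, and 155 matched neither; that table was used for names and gene types only, and no coordinate was taken from it. As deposited, 4 gene names on 11 regions had been turned into dates by a spreadsheet and were left as they stood. There were 363 regions on the sex chromosomes, and not all genes there were eligible to be named.

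Gene lists, groups, tests, alternative settings and the rule for named genes were fixed before the data were examined. The 15 lists held 410 genes: vitamin D receptor targets and metabolism, IL-10 and STAT3 signalling, costimulation and maturation, coinhibition and tolerance, MHC class II and antigen presentation, TLR4 and NF-kB signalling, interferon response, cytokines and chemokines, monocyte and macrophage genes, DC and myeloid transcription factors, DNA methylation machinery, glycolysis and energy metabolism, and markers of T and NK cells, of B and plasma cells, and of granulocytes and platelets. The rule named the 10 largest differences in each direction (once per gene), the 5 genes with the most regions (6 because of a tie), up to 4 members of each list with the largest difference, and the 5 largest promoter differences in each direction. CD163, VDR, CYP24A1, CD14, IL10, CD83, CD86 and CD274 were looked up whatever their value. Other regions of a gene so named are given too.

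Shares have 95% Wilson intervals and medians 95% intervals from order statistics, both over regions. Direction by annotation class, chromosome and list was tested with a two-sided Fisher's exact test against all other regions or genes, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. For lists, a gene took the direction of its largest-difference region. Planned comparisons of list membership with random gene sets matched on length were not run, since they need an annotation of the build of the table, which was not used here. The list test was tested on simulated data, with directions drawn at known shares for lists of 4, 12, 40 and 200 genes among the 3729; with no true shift it called at most 1% of 100 simulations. Alternatives were differences of at least 20 or 30 points, at least 5 or 10 CpG sites, merging of same-direction regions within 1000 bp, autosomes only, gene assignment within 10 kb or by promoter only, and direction by the majority of a gene's regions. Analyses used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 (stratified odds ratios, Mantel-Haenszel) and Matplotlib 3.10.9.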

Results

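DNA methylation was measured by whole-genome bisulfite sequencing in dendritic cells (DCs), the antigen-presenting cells that start T cell responses, grown for 7 days from human blood monocytes. The study compared regulatory DCs (DCreg), conditioned with vitamin D3 and IL-10, with mature DCs (mDC), which were matured with monophosphoryl lipid A, a low-toxicity ligand of the receptor TLR4. There were 6 DCreg and 6 mDC libraries from the same donors. The values are the authors' methylation level of each group, taken here as its mean, over 7279 regions that they called as different between the groups, in hg19 coordinates. No values per library were used, so no level below carries a replicate error, and the read depth behind the levels is unknown. Differences are DCreg minus mDC in percentage points, so a negative value means a lower level in DCreg.

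The question put to the data was where methylation was higher or lower in the regulatory cells than in the mature cells. Among the largest differences towards lower methylation, the lowest level in DCreg lay 66.1 kb upstream of BCL6, a transcriptional repressor of B and T cell differentiation (chromosome 3, 187529584 to 187529875), where the mean level was 55.9% in mDC and 8.60% in DCreg. The largest difference towards lower methylation was at the promoter of RASA4, a Ras GTPase-activating protein (chromosome 7, 102133879 to 102134021), with 96.2% in mDC and 48.6% in DCreg. This promoter region was not screened for copies of its sequence elsewhere in the genome. An intergenic region 83.5 kb upstream of INHBA, which encodes a subunit of activin A (chromosome 7, 41826245 to 41826310), was at 74.9% in mDC and 35.0% in DCreg. A region 24.4 kb upstream of COLEC12, a scavenger receptor (chromosome 18, 525102 to 525184), was at 65.2% and 24.2%. In the other direction, the largest difference lay 69.5 kb downstream of MAGEA1, a cancer-testis antigen (chromosome X, 152411968 to 152412067), with 21.0% in mDC and 83.8% in DCreg. The regions named here for BCL6 and RASA4 held 8 CpG sites each, that for COLEC12 9, that for MAGEA1 5 and that for INHBA 4.

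The 10 largest differences in each direction were named, once per gene. The others that were lower in DCreg were named for DMRTC1 (-45.8 points), ZNF75D (-45.2), FAM182B (-45.1), C2CD5 (-41.6), RP11-160C18.4 (-41.3) and HENMT1 (-40.7). The others that were higher in DCreg were named for FAM182B (46.4 points), the zinc finger gene ZFP37 (46.4), RP11-475I24.8 (43.9), FAM156B (41.7), the deubiquitinase gene USP17L10 (39.1), MAGEA11 (38.7), the cathepsin L pseudogene CTSLP7 (36.6), LINC00273 (36.6) and GRAPL (36.4). Of these largest differences, 2 of the 10 lower (BCL6 and FAM182B) and 3 of the 10 higher (FAM182B, ZFP37 and LINC00273) lay in 1 Mb windows that held 10 or more regions. In the authors' deposited table the area statistic, coded mDC minus DCreg, was 59.7 for the BCL6 region, 34.0 for the RASA4 promoter and -21.9 for the MAGEA1 region.

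Over all 7279 regions, 4036 had the higher level in DCreg and 3243 the lower, a share of 55.4% higher (95% Wilson interval 54.3 to 56.6%). Regions lower in DCreg had a median difference of -12.7 points (95% interval of the median -12.9 to -12.4, interquartile range -17.3 to -9.28), with a median level of 91.3% in mDC and 77.6% in DCreg. Regions higher in DCreg had a median difference of 11.3 points (11.1 to 11.5, interquartile range 8.79 to 14.9), with medians of 80.6% in mDC and 92.6% in DCreg. The balance turned with the size of the difference. Among the 2472 regions that differed by under 10 points, 60.5% were higher in DCreg, against 42.0% of the 890 regions that differed by 20 points or more (interval 38.8 to 45.3%) and 38.3% of the 154 that differed by 30 points or more (31.0 to 46.2%). It turned in the same way with the number of CpG sites, from 58.3% of the 3996 regions with 4 sites to 41.0% of the 551 regions with at least 10 (37.0 to 45.2%). Where the mean of both groups was below 40%, 84 of 266 regions were higher in DCreg (31.6%, 26.3 to 37.4%), and where it was above 90%, 1245 of 2058 were (60.5%, 58.4 to 62.6%). These intervals count regions, which the authors had selected for a difference and which are not replicates, so they do not measure variation between donors.

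**Figure D1:**
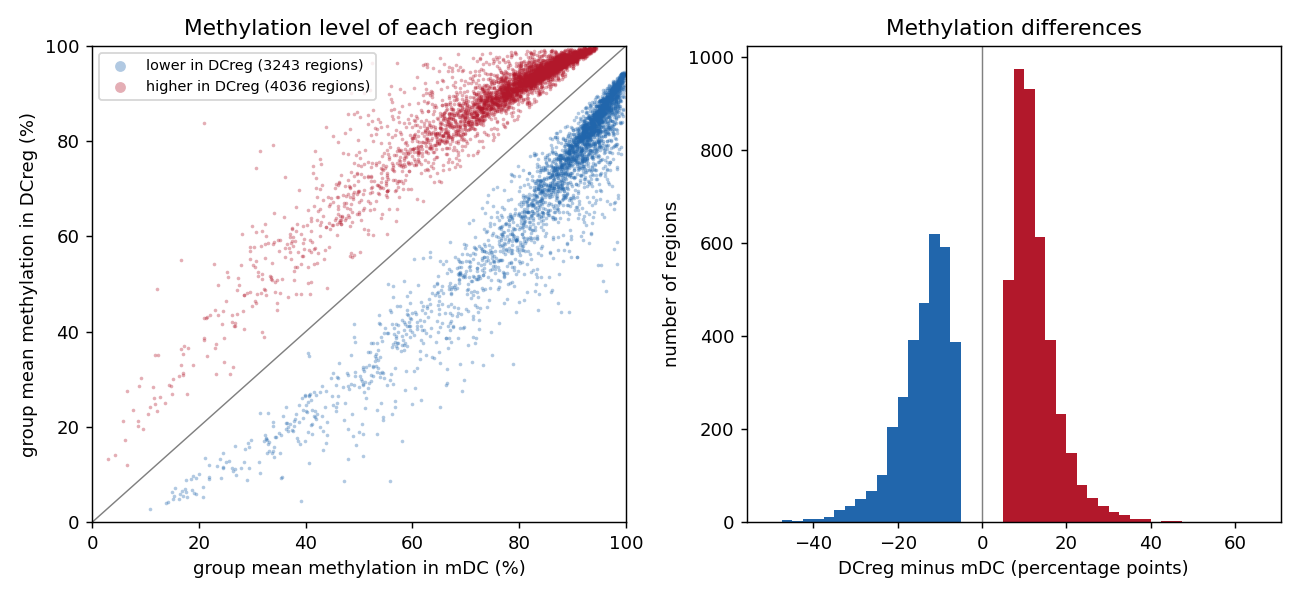
Left, the authors' group mean methylation level of each called region in mDC (x axis, percent) and DCreg (y axis, percent), with 3243 regions lower in DCreg in blue and 4036 higher in red. Right, the number of regions by DCreg minus mDC difference in percentage points; no called region differed by less than 5.0 points, and the largest difference was 62.9.

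**Figure D2:**
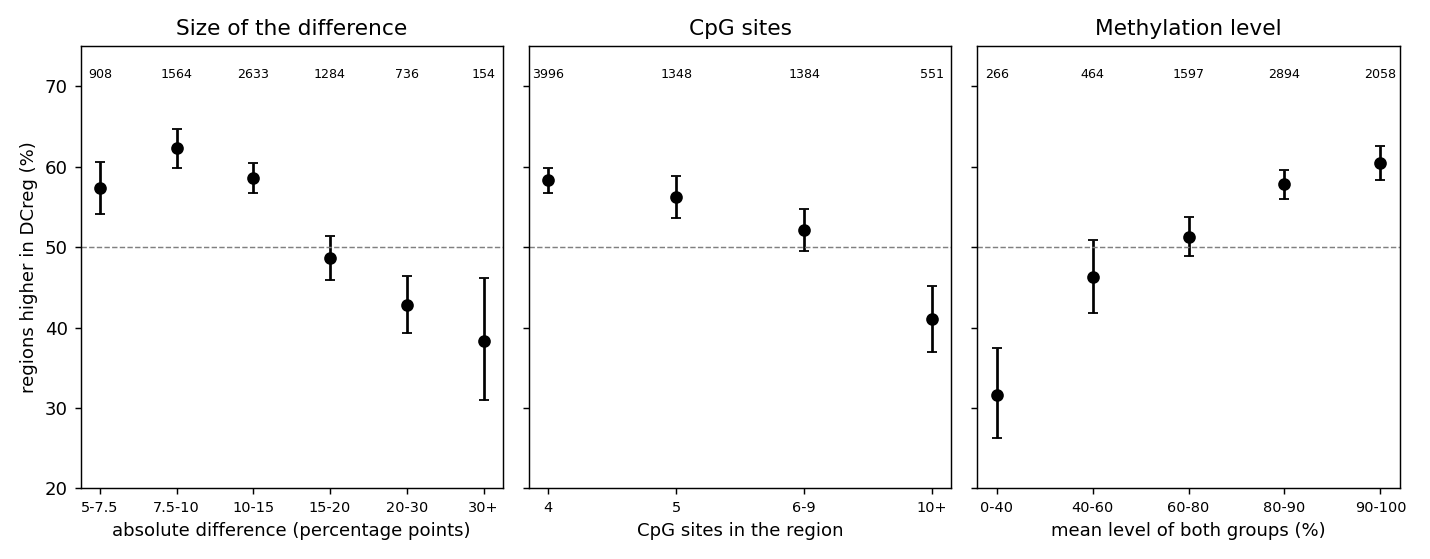
Share of regions with the higher methylation level in DCreg (y axis, percent) by the size of the difference, the number of CpG sites and the mean level of both groups (x axes). Points are shares, bars are 95% Wilson intervals over regions, the dashed line is 50% and the number of regions is printed above each point; the share was 62.3% at 7.5 to 10 points and 38.3% at 30 points or more.

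The position of the regions relative to genes was compared between those higher and those lower in DCreg. Few regions lay within 1 kb of a transcription start site (TSS): 109 of 7279, of which 64 were higher and 45 lower in DCreg. Among them was the promoter of CD274, which encodes the T cell inhibitory ligand PD-L1 (chromosome 9, 5449231 to 5449688, 11 CpG sites, 0.815 kb upstream of the TSS), at 56.2% in mDC and 36.8% in DCreg. Promoter regions with the largest differences towards higher methylation belonged to FAM156B (50.9% in mDC, 90.2% in DCreg), SLFN12L, a member of the Schlafen family (36.0%, 64.2%), FAM115C (29.6%, 56.9%), PABPC1L2B (25.4%, 51.4%) and GTPBP2, a GTP-binding protein (35.3%, 59.3%). Those with the largest differences towards lower methylation belonged, after RASA4, to DDX11L9 (93.8% in mDC, 64.1% in DCreg), SLX1B-SULT1A4 (93.0%, 64.7%), RP11-111F5.5 (35.4%, 9.24%) and the forkhead gene FOXD4L4 (35.6%, 9.51%), the last of these and RP11-111F5.5 in 1 Mb windows with 10 or more regions.

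Regions 1 to 50 kb from a TSS, a class that held the lower regions near CYP24A1 and CD163 and the higher one in LAMP3, were less often higher in DCreg than all other regions (1434 of 2768, 51.8%, against 57.7%; two-sided Fisher's exact test, adjusted p = 7.31e-06). Intergenic regions, a class that held the higher region near MAGEA1 and the lower one near BCL6, were more often higher than all others (1926 of 3299, 58.4%, against 53.0%; Fisher's exact test, adjusted p = 1.69e-05). Promoters (58.7%, Fisher's exact adjusted p = 0.873) and introns (587 of 1056, 55.6%, Fisher's exact adjusted p = 1) did not differ from the rest by this test, and exons held 29 regions, untranslated regions 15 and downstream flanks 3. Among regions with at least 10 CpG sites both differences had the opposite sign and neither passed: 43.3% of regions 1 to 50 kb from a TSS were higher in DCreg (Fisher's exact adjusted p = 0.523) and 33.0% of intergenic regions (Fisher's exact adjusted p = 0.332). Of 24 chromosomes, with shares from 45.3% to 62.5% higher in DCreg, 0 differed from the rest by Fisher's exact test after adjustment (smallest adjusted p = 0.429) and 1 had an unadjusted p below 0.05.

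Genes of the vitamin D pathway were examined because vitamin D3 was part of the conditioning. Of the 24 listed, 4 had a region, and all 8 of their regions were lower in DCreg. CYP24A1, which encodes the hydroxylase that inactivates vitamin D and is a classic target of the vitamin D receptor, had 3 regions downstream of the gene on chromosome 20. The longest, with 26 CpG sites (52740143 to 52740617), was at 82.3% in mDC and 59.3% in DCreg. The others were at 81.2% and 64.3% (52747678 to 52747873) and at 94.8% and 79.8% (52744976 to 52745041), and the 3 regions lay between 22.1 and 29.4 kb beyond the end of the transcript. FN1, which encodes the matrix protein fibronectin, had 3 regions with differences of -24.8, -19.1 and -17.1 points. The first lay 162 kb upstream of the gene. The others were close neighbours inside it (chromosome 2, 216232449 to 216232557 and 216232718 to 216232820). Close neighbours often shared a direction, as given at the end, so the 8 regions are not independent. A region inside HBEGF, an EGF-family growth factor (chromosome 5, 139718373 to 139718560), was at 73.3% in mDC and 51.9% in DCreg, and a region 11 kb upstream of FBP1, a gluconeogenic enzyme also counted below under energy metabolism, differed by -11.7 points. VDR, the receptor itself, had 0 called regions.

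Direction was tested per list over genes, each taken by its largest-difference region. Over all 3729 genes with a region, 1743 were lower in DCreg (46.7%), against 4 of 4 in the vitamin D list (Fisher's exact test, p = 0.0476, adjusted p = 0.334 over 14 lists). The same balance was found for markers of granulocytes and platelets, cells that were not the target of the culture, with 4 of 4 lower at CCR3 (-16.4 points), CSF3R (-11.9), CLC (-11.2) and CXCR2 (-10.8), at the same p by Fisher's exact test (p = 0.0476, adjusted p = 0.334). Of the 14 lists tested, 0 passed after adjustment and 2 had an unadjusted p below 0.05. In simulated data on 3729 genes, a list of 4 genes with 95% of them lower was called in 0% of 100 simulations, and a list of 12 genes in 92%. With 80% lower, a list of 12 genes was called in 25%, and no list here had more than 12 genes with a region. The shortest lists therefore could not pass, and a moderate shift of the longer ones would mostly have been missed.

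Surface molecules that drive or restrain T cell activation were compared as 2 lists. Among 23 genes of costimulation and maturation, 5 had a region, with 1 gene lower and 4 higher in DCreg (Fisher's exact test, p = 0.380, adjusted p = 0.887). LAMP3, a lysosomal protein of mature DCs, had a region inside the gene (chromosome 3, 182876049 to 182876337) at 33.9% in mDC and 58.3% in DCreg. CD1C, a lipid antigen-presenting molecule of DCs, had 2 downstream regions, the nearer one (chromosome 1, 158266193 to 158266298) at 65.3% and 91.0% and the other with a difference of 9.22 points. The region named for BIRC3, an inhibitor of apoptosis induced by NF-kB, was 11.8 points higher. CD83, a marker of mature DCs, was the gene that was lower, by a region (chromosome 6, 14676332 to 14676493) at 83.4% and 60.2% that lay 539 kb downstream of it. CD86, a ligand of CD28, had 0 called regions.

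Among 26 genes of coinhibition and tolerance, 11 had a region, 6 lower and 5 higher (Fisher's exact adjusted p = 1). Both ligands of the inhibitory receptor PD-1 were among the lower genes: CD274 at its promoter, as above, and PDCD1LG2 by a region inside the gene (chromosome 9, 5545833 to 5546011) at 58.2% in mDC and 38.2% in DCreg. LILRB4, an inhibitory receptor of myeloid cells, had the largest difference of the list, at 83.7% and 47.8% (chromosome 19, 55184715 to 55184785, 4 CpG sites, 4.87 kb downstream of the gene). LGALS9, which encodes galectin-9, had 2 regions with differences of -19.2 and -16.0 points. These genes were named for the largest differences of the list, and the 5 higher genes had smaller ones. Of all 18 regions of the list, 10 were lower and 8 higher. Of 22 genes of MHC class II and antigen presentation, 0 had a called region, and that list was not tested.

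Signalling through IL-10 and TLR4 was examined because the protocols used ligands of both receptors. Of 18 genes of IL-10 and STAT3 signalling, 2 had a region, 1 in each direction (Fisher's exact adjusted p = 1). DUSP1, a phosphatase that restrains MAP kinases, had 3 upstream regions with differences of 18.8, 16.8 and -14.5 points, and NFIL3, a transcription factor induced by IL-10, had a region at -16.4 points. Of 28 genes of TLR4 and NF-kB signalling, 8 had a region, 4 in each direction (Fisher's exact adjusted p = 1). IKBKG, the regulatory subunit of the IkB kinase, was at 86.0% in mDC and 48.3% in DCreg (chromosome X, 153786602 to 153786797, inside the gene), whereas TNFAIP3, which encodes the NF-kB inhibitor A20, had 2 upstream regions that were higher by 16.2 and 15.1 points. MAP3K7 (-14.96 points) and TNIP1 (-14.5) were lower. Of 38 interferon response genes 1 had a region, IFI44, at 11.7 points (Fisher's exact adjusted p = 1). IL10 had 0 called regions.

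Of 34 cytokines and chemokines, 7 had a region, 4 lower and 3 higher (Fisher's exact adjusted p = 1). INHBA had 4 regions upstream of the gene, of which the 3 farther ones were lower (-39.9, -30.2 and -19.7 points) and the one 1.49 kb from the TSS was higher (16.0 points). EDN1, which encodes endothelin, had 2 lower upstream regions, the larger (chromosome 6, 12233634 to 12234060, 20 CpG sites) at 65.0% in mDC and 35.8% in DCreg. A region 19.8 kb downstream of CXCL8, a neutrophil chemokine named IL8 in the authors' table (chromosome 4, 74629200 to 74629383), was at 66.3% and 38.7%. A region 12.3 kb downstream of the chemokine gene CCL4 (chromosome 17, 34445335 to 34445398, 4 CpG sites) was at 59.4% and 87.7%.

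Monocyte and macrophage genes went both ways: 11 of 32 had a region, 5 lower and 6 higher (Fisher's exact adjusted p = 1). CD163, a haemoglobin scavenger receptor whose protein the study stained, had a region 9.12 kb upstream of it (chromosome 12, 7665530 to 7665596, 4 CpG sites) at 41.7% in mDC and 23.3% in DCreg. CD36, a scavenger receptor for lipids, had 4 regions with differences of -32.2, -12.5, -10.1 and 9.27 points. Only the higher one was inside the gene, and the lower ones lay 37.2 to 48.5 kb downstream of it. FCGR2A, an activating Fc receptor, had 2 upstream regions of opposite direction, at 68.8% and 40.8% (chromosome 1, 161420599 to 161420885, 42 CpG sites) and at 21.3% and 42.9% (161425840 to 161425968, 24 CpG sites). MRC1, the mannose receptor, was higher at both of its regions (20.6 and 10.9 points), and MAF, a macrophage transcription factor, had regions at 20.6, -10.7 and 8.44 points. Of the MAF regions only the lower one was inside the gene, and the higher ones lay 156 and 351 kb downstream. CD14, the coreceptor of TLR4, had 0 called regions.

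Of 38 transcription factors of DCs and myeloid cells, 12 had a region, 5 lower and 7 higher (Fisher's exact adjusted p = 1). All 5 regions named for PRDM1, a repressor that restrains DC activation, were higher in DCreg, by 8.60 to 17.6 points. They lay 26.9 to 284 kb from its TSS, and 1 of them (chromosome 6, 106635550 to 106636171) lay in an intron of ATG5. A region of 20 CpG sites downstream of FOSL2, an AP-1 family member (chromosome 2, 28667791 to 28668569), was at 69.6% in mDC and 41.0% in DCreg. RUNX1 had regions at -20.3 and 12.5 points, the latter in an intron, and ETV6 a region at 19.8 points. Of 21 genes of the DNA methylation machinery, 3 had a region and all 3 were lower by their largest difference (Fisher's exact test, p = 0.102, adjusted p = 0.476). These were ZBTB38, a reader of methylated DNA (chromosome 3, 141050600 to 141051005, 71.6% in mDC and 48.6% in DCreg), and the demethylating dioxygenases TET2 (-8.80 points, with a further region at 6.14) and TET3 (-6.53). The TET2 regions lay 89.6 and 225 kb upstream of the gene.

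Of 28 genes of glycolysis and energy metabolism, 7 had a region, 4 lower and 3 higher (Fisher's exact adjusted p = 1). PPARGC1B, a coactivator of mitochondrial genes, had regions at -22.2 and -18.8 points, HIF1A, the oxygen-regulated activator of glycolysis, a region inside the gene at -17.5, and SLC2A3, a glucose transporter, a region at -16.4. Markers of lymphocytes, which the culture was not meant to contain, were also counted. Of 34 T and NK cell genes, 8 had a region, 6 lower and 2 higher by their largest difference (Fisher's exact adjusted p = 0.551), with the largest at CD28 (85.7% in mDC, 51.4% in DCreg). All regions of that list were 7 lower and 8 higher, and by the majority of a gene's regions 40% of 5 genes were lower (Fisher's exact adjusted p = 1). NCAM1 had regions at -25.3 and 9.97 points, CTLA4 at -22.5 and 17.9, and GATA3 5 regions from -19.1 to 9.02. Those of GATA3 lay 384 to 1128 kb downstream of the gene. Of 22 B and plasma cell genes, 2 had a region, and both were lower by their largest difference (Fisher's exact adjusted p = 0.612): EBF1, with regions at -13.4, 8.24 and -5.65 points, and BANK1, with 4 regions from -10.9 to 8.07. In all, 84 of the 410 listed genes had a region. Absence from the table shows only that no region was called near a gene, and 36 of the 84 had a region inside the gene or within 10 kb of its TSS.

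**Figure D3:**
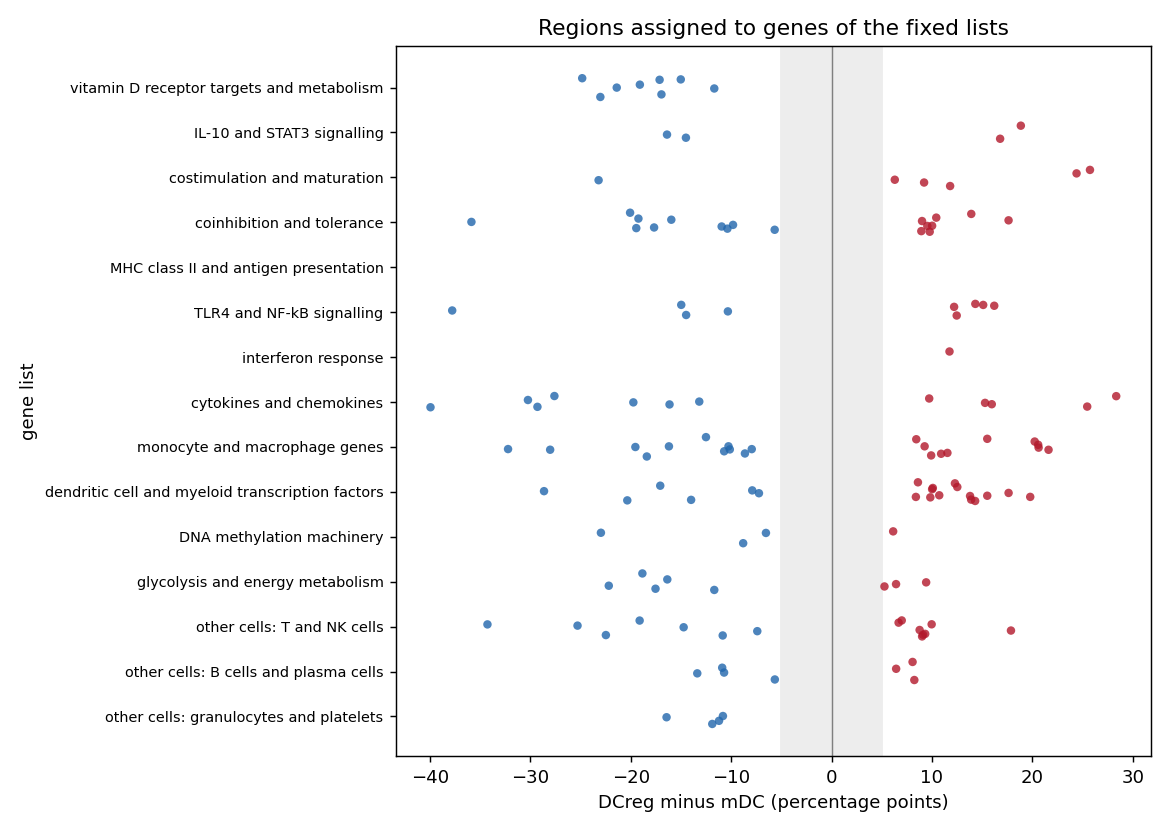
Each point is a called region named for a gene of the fixed list on the y axis, at its DCreg minus mDC methylation difference (x axis, percentage points); blue points are lower and red points higher in DCreg. The grey band spans differences below 5.0 points, where no region was called. All 8 regions of the vitamin D list, which belong to 4 genes, and all 4 of the granulocyte and platelet list lie to the left of it.

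The genes named most often were FAM182B, with 33 regions (21 higher and 12 lower in DCreg), the adhesion receptor gene LPHN3, with 19 (11 higher, 8 lower), and the protocadherin gene PCDH7, with 17 (9 higher, 8 lower). BRINP3 (11 higher, 5 lower), AC098817.5 (8 higher, 8 lower) and RP11-475I24.8 (9 higher, 7 lower) had 16 each. All of these went both ways, and their regions are named by the nearest transcript, which for the largest difference of FAM182B lay 246 kb away. The largest higher and lower differences of FAM182B were nearest to separate transcripts on chromosome 9, starting at 44990236 and 45727029. This name therefore does not stand for a single place in the genome.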

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

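Leaving out 1 Mb windows with 10 or more regions, and leaving out regions whose area statistic had the opposite sign, were chosen after the data had been seen; the other settings were planned. No paired analysis was possible because the table holds group means only, and leaving out libraries, a coverage minimum and random gene sets were not run. The share of regions higher in DCreg was between 55.3% and 55.9% after merging, on autosomes and under both later settings, against 55.4%. It was 52.0% with at least 5 CpG sites, and turned to 41.0% with at least 10, 42.0% at 20 points or more and 38.3% at 30 or more; the cause was not tested beyond the stratified odds ratios given later. The median difference of lower regions was -15.04 and -19.3 points in these CpG classes and -23.7 and -33.6 in these size classes, that of higher regions 12.5, 17.8, 23.6 and 33.6, which follows from the selection for the size classes; on autosomes the median of higher regions was 11.1. For position, 2 classes passed except at 30 points or more and at 10 or more CpG sites, where 0 did. There, 1 to 50 kb from a TSS, 36.3% and 43.3% of regions were higher in DCreg (Fisher's exact adjusted p = 1 and 0.523, range over all settings 8.68e-07 to 1), and of intergenic regions 40% and 33.0% (Fisher's exact adjusted p = 1 and 0.332, range 1.18e-05 to 1). The latter values of both classes, at 10 or more CpG sites, reversed the difference from other regions; fewer regions were tested, and the cause of the reversal was not tested. For chromosomes, 1 (a sex chromosome) passed at 20 points or more, where 45 of its 74 regions were higher in DCreg (39.2% lower against 59.7% elsewhere, Fisher's exact adjusted p = 0.0196), for an untested cause, and 0 in all other settings. Of the 84 listed genes with a region, 26 had one at 20 points or more, 5 at 30 or more, 20 with at least 10 CpG sites, 36 inside the gene or within 10 kb and 2 at a promoter, since fewer regions enter. No list passed in any of 123 alternative values (smallest Fisher's exact adjusted p = 0.274), and 14 of these turned the balance of a list, among them that of T and NK cell genes by the majority of regions (40% of 5 genes lower). Of 114 named regions, 54 remained at 20 points or more and 29 with at least 10 CpG sites. Unknown coverage limits all levels.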

Other observations

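The counts of genes whose regions all went 1 way, the comparison of neighbouring regions and the choice of genes named in this part came only after the results were seen. Upstream of BCL6, 5 of 6 regions were lower in DCreg, 18.4 to 113 kb from the TSS, and the most distant, 177 kb away, was 5.85 points higher. They belong to a stretch of chromosome 3 (187133940 to 187873066) with 11 regions, 9 of them lower, that runs towards LPP. All 4 regions inside MAP7, a microtubule-associated protein, were lower, the largest at 90.8% in mDC and 55.7% in DCreg (chromosome 6, 136760517 to 136760697). Those starting at 136760517, 136761057 and 136761303 were close neighbours, so they may be a single stretch split by the caller. ANXA1, the glucocorticoid-induced protein annexin A1, had 4 lower regions, 22.1 to 660 kb from its TSS. The nearest was at 65.7% and 48.1% (chromosome 9, 75794669 to 75794843). FAM20C, a secretory kinase, had 5 lower regions from -28.2 to -13.0 points, 21.1 to 179 kb from its TSS.

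Of the 109 promoter regions, a few more are given here, picked by hand with no test of a shared theme. The promoter of ACSL1, a fatty acyl-CoA synthetase of inflammatory macrophages (chromosome 4, 185733609 to 185733688), was at 72.8% in mDC and 51.3% in DCreg, that of the cathepsin gene CTSK at 91.9% and 76.8%, and that of CPVL, a carboxypeptidase of macrophages and DCs, at 16.9% and 6.51%. The promoter of CDKN1A, which encodes the cell cycle inhibitor p21 (chromosome 6, 36643855 to 36644093), was at 52.3% in mDC and 71.7% in DCreg. That of GPNMB, a glycoprotein of lipid-laden macrophages, was at 34.6% and 46.1%, and POR, the electron donor of cytochrome P450 enzymes, was higher at both promoter regions, by 18.7 and 13.7 points. These regions hold 4 to 8 CpG sites each.

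Large differences were more often lower in DCreg: the odds of being lower were 1.85 times as high at 20 points or more as below (95% interval 1.61 to 2.14). An exception was 1 sex chromosome, where 45 of 74 such regions were higher in DCreg. Within classes of methylation level the odds ratio was 1.43 (1.22 to 1.68), and within classes of CpG number 1.64 (1.41 to 1.90). Neither alone, in these classes, accounted for all of it, and level and CpG number together lowered it to 1.30 (1.10 to 1.54). The classes were wide, the last of CpG number running from 10 to 150 sites, and the intervals count regions as independent. Level and CpG number together are therefore not excluded as the source of the remainder. The caller's thresholds, bisulfite conversion and a biological effect of the conditioning stay open and were not tested.

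Large differences also gathered in few places: 35 of 2459 windows of 1 Mb held 10 or more regions, 429 regions in all (5.89%), and 26 of the 100 largest differences. In these windows 36.1% of regions differed by 20 points or more, against 10.7% elsewhere, and 12 of the windows lay on chromosome 9. Within classes of CpG number the odds ratio was 4.19 (3.34 to 5.26) against 4.71 without them, so CpG number, in these classes, does not account for all of this. Whether regions in these windows held fewer or more CpG sites was not examined. Regions there were named for a pseudogene more often, 15.4% against 4.20% (Fisher's exact test over regions, p = 1.40e-13). Reads shared between duplicated sequences are therefore a candidate explanation. The p-value counts regions as independent, although 1 name can recur: ZNF733P was the only name in chromosome 7 windows of 12 and 10 regions. Names were not counted once each. Levels in these windows, FAM182B and FOXD4L4 among them, may therefore mix several copies, and a biological difference there was not tested. The BCL6 window is among the 35, with regions named for BCL6, LPP, LPP-AS2 and RTP4. Regions outside these windows were not screened for copies and may share this limit. They include those of RASA4 and IKBKG, in windows of 2 and 7 regions. FAM156B, for example, in a window of 5 regions, was named from transcripts that do not overlap (starting at 52928085 and 52976464).

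Of 390 genes with 4 or more regions, 50 had all of them in the same direction, against 32.3 when directions were shuffled among regions of similar level and distance to a TSS (permutation p = 0.00160), and the test was then split by direction. All regions were higher in DCreg for 39 genes against 25.3 in shuffled data (permutation p = 0.00370), among them HTR1B with 8 regions, the semaphorin SEMA6D with 6, PRDM1 with 5, and STIM2 and CTIF with the largest medians of the set, 19.5 and 21.1 points. A split of single regions by the caller did not account for it, with 35 genes against 24.8 after merging within 1000 bp (permutation p = 0.0197). Genes were counted by name, so 1 name can pool separate places. OR4F16, among the 39, had regions at positions from 384670 to 180812873. The regions of HTR1B ran from 77532160 to 78839617. For SEMA6D and STIM2 even the nearest region lay 61469 and 65901 bp from a TSS, so these names stand for the nearest transcript only. For regions all lower, 11 genes against 6.94 in shuffled data (permutation p = 0.0895) leave chance open, which covers MAP7, ANXA1 and FAM20C. After merging within 1000 bp, 8 genes were all lower against 6.53 in shuffled data (permutation p = 0.333). Neighbouring regions shared a direction in 87.8% of pairs up to 1 kb apart (95% Wilson interval 79.0 to 93.2%), 59.5% at 1 to 10 kb (54.2 to 64.6%), 55.1% at 10 to 100 kb (52.8 to 57.5%), 52.9% at 100 to 300 kb (50.8 to 55.1%) and 50.5% beyond (48.7 to 52.2%), against 50.6% by chance, so neighbours are not independent as the shuffling takes them to be, and how much of the excess this leaves is open.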
